A study of Beauveria bassiana with 4 samples.

How the data were processed

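The deposited table held 1 column of values per library for 4 libraries of messenger RNA (oligo(dT) enrichment, fragments of about 200 bp, Illumina HiSeq 2000, per the labels' protocols): 1 described as an agar culture and 3 as infections at 24, 48 and 72 h. The authors' values are FPKM, as the deposited column names state. Cufflinks 2.0.1 is named per the submitters' processing notes, which also give the mouse genome build mm9; because the genes listed are fungal, no coordinates are printed here. The aligner is not given in the sources used here, and nor is whether the clean reads were sorted by organism before counting. The deposited header block also holds other values, the read statistics of each run, from which the clean reads were taken. Per the file headers, the authors discarded reads with unknown bases, low quality or adapter before alignment.

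All 8506 gene identifiers in the table, and their transcript accessions, matched the reference gene table of the assembly ASM28067v1, which lists 10364 genes. That table gave locus tags, the order of neighbouring genes and gene lengths. Names are those the deposited table pairs with each identifier, and 1587 genes had no functional name. The 0 h column matches no label word for word. It was assigned to the agar culture as the only sample without an infection time, and every direction against it rests on that assignment.

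FPKM is not a count, so no count model was used. The low values nevertheless fell on steps: in each library, FPKM times gene length less 36.5 bases clustered at whole multiples of 1 value, that of a single read. Among genes at about 1 to 3 reads with a length that is a multiple of 3, as genes without introns have, 49.8% to 63.3% were whole within 0.02 reads, against 0.648% to 1.75% of genes of other lengths. The step gave the number of reads on genes per library, and each gene's FPKM was turned into estimated reads that add up to it. This needed a scale factor of 1.19 to 1.23, whose cause was not tested. Every gene was divided by it alike, so a gene on a whole step has an estimate below that whole number of reads. Ratios of estimated reads carry exact conditional binomial (Clopper-Pearson) 95% intervals, and levels of lists carry exact Poisson intervals. Both use rounded estimates and cover counting error only. The floor of 3 reads on a gene of 1500 bases was 92.9, 35.3, 3.45 and 3.29 FPKM at 0, 24, 48 and 72 h.

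With 1 library per group there was no test. A gene was called higher or lower by a rule of size: log2((a + 1)/(b + 1)) of at least 2 in either direction, a and b being FPKM, among the 7247 genes with a mean of at least 5 FPKM over the 4 libraries. Folds on that scale understate the difference of low genes, so the folds printed are ratios of FPKM, or of pooled estimated reads for lists, and none is given against a library listed at 0. For each of 35 gene lists, chosen by name patterns, the median log2 ratio of the compared members was ranked among 10000 random lists of the same size matched on mean FPKM in 10 bins, and a list was said to stand apart under percentile 2.5 or over 97.5, as a description of these libraries. Pooled reads use every member of a list, whether or not it passed the minimum. Against the shallow 0 h library a gene with a low mean passes the minimum mostly when it happens to have a read there, so a pooled ratio and its interval are given beside the medians quoted against 0 h.

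The genes named are, per comparison with 0 h, the 10 highest and 10 lowest log2 ratios among genes with a functional name that passed the size rule, 5 and 5 for successive times, up to 4 members per list with the largest ratio against 0 h, and up to 2 genes without a functional name in each direction. BBA_04860, the genes named only as neighbours of others, and BBA_05021, BBA_01125 and BBA_07138, named for their weight in their lists, were chosen after their values were seen. The comparisons, the size rule, the lists, the rule for named genes and 8 alternatives (pseudocounts of 0.1 and 5, no minimum, a minimum of 20, a 2-fold rule, median-of-ratios scaling, TMM scaling, and the top 1% of genes left out of the totals) were fixed before the data were examined. The requirement that the interval exclude 1 was added after the data were seen. So were the restriction to genes above 0 in both libraries and the scaling without genes conserved between fungus and insect. The pooling of lists without the gene of largest change, or without 2 or 3 conidial wall proteins, was also added then. Estimating reads from the steps of FPKM was not in the plan fixed beforehand, and neither were the pooled levels and ratios of lists.

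For each comparison, 100 pairs of libraries with no difference were drawn from the pooled rate of each gene and counted by the same size rule and interval. For the overlap between times, 100 sets of 4 libraries were drawn from 1 shared rate. The minimum was not applied anew to the draws, which used the 7247 genes that passed it in the observed libraries. Selection of genes by a read at 0 h is therefore not reproduced in the draws. The procedures were tested on simulated data with 200 of 7247 genes changed 8-fold or 16-fold. Of genes made 8-fold higher, the size rule with the interval recovered 35.8%, 41.2% and 25.0% in the comparisons of 24, 48 and 72 h with 0 h, 64.9% from 24 to 48 h and 89.1% from 48 to 72 h. Of genes made 8-fold lower it recovered 49.2%, 57.1%, 40.5%, 81.6% and 87.7%, and of genes made 16-fold lower 62.8%, 65.1%, 56.0%, 92.7% and 95.0%. Of genes made 16-fold higher it recovered 39.0%, 26.6%, 43.3%, 66.0% and 100% in the same order. It called 48, 52, 44, 32 and 14 of the 7047 unchanged genes. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. TMM and median-of-ratios scaling were written out in numpy and applied to FPKM. Median-of-ratios scaling rests on genes above 0 in every library, and TMM scaling on genes above 0 both in the library scaled and at 72 h. The shallow 0 h library limits both sets.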

Results

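The series followed Beauveria bassiana strain ARSEF 2860, a fungus that kills insects by growing through the cuticle into the body cavity, on its wax moth host Galleria mellonella and on agar. Messenger RNA was sequenced from 4 libraries. The labels describe 1 as a culture grown for 12 days in the dark at 28 °C on potato dextrose agar until the mat reached 8 cm, and the others as the fungus at 24, 48 and 72 h of infection, with the host labelled live at 24 and 48 h and dead at 72 h. Each group was 1 library, so no difference below has a replicate check, no test between conditions was possible, and the intervals given cover counting error only. The table names its columns 0, 24, 48 and 72 h. The 0 h column was taken as the agar culture because no other sample lacks an infection time, and it is called the library labelled 0 h throughout.

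The table gave FPKM (fragments scaled by transcript length and by the mapped total of the library) for 8506 genes, and 4938, 5882, 8013 and 7932 of them were above 0 at 0, 24, 48 and 72 h. The libraries held 23532535, 23816156, 23884875 and 23898669 clean reads of 50 bases. The spacing of the low FPKM values gave an estimated 22072, 57999, 594893 and 622330 reads on fungal genes, which were 0.0938%, 0.244%, 2.49% and 2.60% of the clean reads. A single read on a gene of 1500 bases was thus worth 31.0 FPKM at 0 h, 11.8 at 24 h, 1.149 at 48 h and 1.098 at 72 h. Actin (BBA_04860), a part of the cytoskeleton in fungus and insect alike, stood at 133489, 58066, 7816 and 5721 FPKM. Together with 4 tubulin genes it took 25.6%, 12.0%, 1.72% and 1.31% of the reads on fungal genes. The list of 27 genes conserved between fungi and insects, which includes these, took 28.3%, 15.2%, 4.18% and 4.35%. Over genes above 0 in both libraries, the rank correlation across genes (Spearman) was 0.915 between 48 and 72 h, 0.776 between 24 and 48 h, and 0.517, 0.470 and 0.444 between 0 h and the 3 infection times, with genes not being independent replicates.

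**Figure D1:**
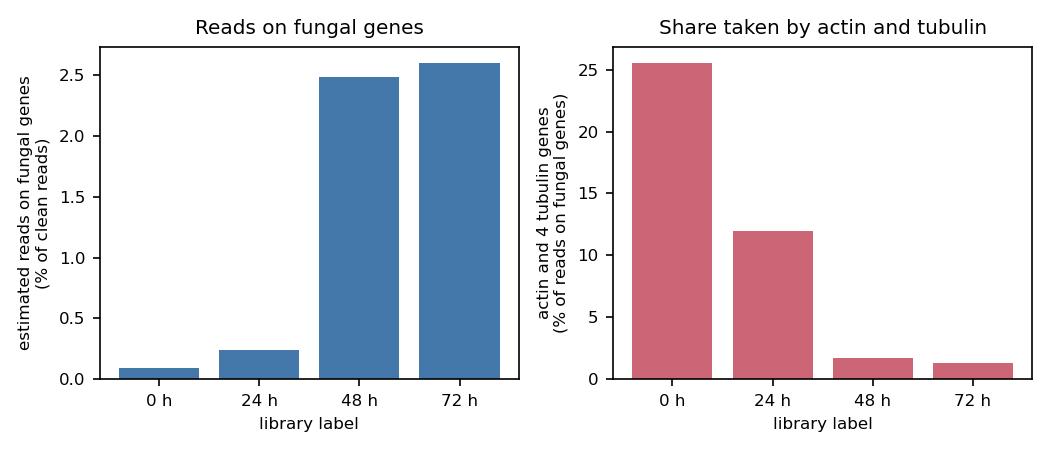
Estimated reads on fungal genes as a percent of the clean reads (left) and the percent of those reads on actin and 4 tubulin genes (right), 1 bar per library by its label. The left bars stand at 0.0938%, 0.244%, 2.49% and 2.60%, and the right bars at 25.6%, 12.0%, 1.72% and 1.31%.

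The comparison of 24 h of infection with the library labelled 0 h asked which genes differed early in the live host, as far as that label stands for the agar culture. Genes of protein synthesis stood higher at 24 h. Ribosomal proteins, a list that by name also holds some of the mitochondrial ribosome, took 143041 RPM (estimated reads scaled to the same total in every library) against 34847, 4.10-fold more (95% counting interval 3.81 to 4.43), and their median log2 ratio of 1.99 lay above every one of the 10000 random lists. Of 111 members compared, 42 were higher by the size rule with an interval excluding 1, and 1 was lower. Ribosomal L29e (BBA_09978), L26 (BBA_06177) and L38e (BBA_07821) were listed at 0 at 0 h and at 3203, 3039 and 1152 FPKM at 24 h.

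Pooled reads of the iron and glycolysis lists were also higher at 24 h. The 32 genes of iron acquisition took 5.65-fold more reads (3.94 to 8.56), although only 4 of 27 compared members were higher with an interval excluding 1 and 2 were lower. Their median log2 of 3.35 (percentile 99.1) did not stand apart without the minimum (percentile 46.8). Without the ornithine monooxygenase BBA_05021, the member of largest change, the pooled ratio was 3.25 (2.25 to 5.04). The siderophore iron transporter BBA_05827, which imports iron bound to a small chelator, was listed at 0 at 0 h and at 1132 FPKM at 24 h. The iron permease of the FTR1 family BBA_04575 stood at 0 and 1195, while the ferric-chelate reductase BBA_00704 stood at 339 and 0. The siderophore synthesis gene BBA_06995 was at 0 and 155 FPKM, but its interval included 1. Glycolysis and gluconeogenesis genes took 3.67-fold more reads (2.81 to 4.86), with 6 of 21 compared members higher and none lower by the rule with the interval, and a median log2 of 3.02 (percentile 99.1). Triosephosphate isomerase BBA_05998 was listed at 0 at 0 h and at 752 FPKM at 24 h. The proteasome list, the machinery that breaks down tagged proteins, had a median log2 of 1.40 (percentile 99.6) and took 1.73-fold more reads (1.27 to 2.36), with 1 of 37 members higher and 2 lower by the interval. With conserved genes left out of the totals the interval of that ratio, 1.26, included 1.

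Secreted enzymes gave a mixed picture at 24 h. Subtilisin-like proteases, which digest the protein of insect cuticle, took 6.69-fold more reads (3.61 to 13.5) at 24 h, with 3 of 13 compared members higher and none lower, and a median within the random range (percentile 90.0). Without BBA_08791 the ratio was 4.02 (2.14 to 8.19). BBA_08791, by name the alkaline serine protease AorO, and the subtilases BBA_02214 and BBA_06292, all listed at 0 at 0 h, stood at 771, 296 and 187 FPKM. Membership of the subtilisin-like list rests on names alone. The trypsin-like protease BBA_09334 was at 0 and 669.9 FPKM, and tripeptidyl peptidase BBA_07294 at 0 and 459. Laccase and pigment genes took 13.4-fold more reads (4.94 to 48.2) with a median within the random range (percentile 45.4), led by the multicopper oxidase BBA_04576 (0 and 901 FPKM), without which the ratio was 5.14 (1.82 to 18.8), and tyrosinase 2 BBA_04061 (0 and 308). The laccase and pigment ratio rested on few reads at 0 h, where the list held 175 RPM (49.4 to 464). Chitinases had a median log2 of -1.92 (percentile 2.43, but 7.1 without the minimum), while the interval of their pooled ratio included 1 (1.00, 0.625 to 1.60). That ratio ranged from 0.735 to 1.76 across scalings, with an interval excluding 1 under TMM scaling, and was 0.480 (0.281 to 0.826) without BBA_03814. BBA_03814 was at 0 and 851 FPKM while by the interval 3 of 17 compared members, among them BBA_06317 (224 and 0 FPKM), were lower and 2 higher. BBA_06317 rested on an estimated 4.1 reads at 0 h. The lipase and cutinase median was lower as well (log2 -2.30, percentile 0.09, but 6.8 with a minimum of 20 FPKM), with BBA_07796 at 0 and 563 FPKM and BBA_08423 at 166 and 0, and its pooled ratio of 0.638 (0.435 to 0.952) was 0.399 (0.257 to 0.616) without BBA_07796 and ranged from 0.467 to 1.12 across scalings. BBA_08423 rested on an estimated 3.9 reads at 0 h.

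Some genes of the spore and its wall were among those higher at 0 h. The class I hydrophobin BBA_03015, one of the small proteins that coat spores with a water-repellent layer, had 27219.7 FPKM at 0 h and was listed at 0 at all 3 infection times. The conidial wall proteins BBA_03994 and BBA_09998 had 9786 and 9326 FPKM at 0 h and were listed at 0 at 24 h. The conidiation list was 4.13-fold lower in pooled reads (3.12 to 5.50), with 3 of 9 compared members lower and 1 higher by the interval. The fold rested on the conidial wall proteins, of which BBA_07138 went the other way (129 and 4329 FPKM), and without all 3 the ratio was 0.758 (0.292 to 2.65). The hydrophobin and adhesin list was 12.3-fold lower (9.03 to 16.7) through BBA_03015, since the adhesin BBA_03909 went the other way (131 and 722 FPKM). The adhesins Mad1 (BBA_02419) and Mad2 (BBA_02379) stood at 74.5 and 208 and at 58.8 and 44.8 FPKM, with intervals that included 1. Other genes named at the low end at 24 h were the allergen-like BBA_02580 (2325 and 0 FPKM), Bys1 family BBA_03338 (2220.3 and 0), peptidase A4 BBA_02028 (945 and 0), the CHCH domain gene BBA_05698 (757 and 0), zinc-binding dehydrogenase BBA_08439 (671 and 0), the HIT domain gene BBA_10210 (646 and 0) and alcohol dehydrogenase BBA_02281 (618 and 0). The unnamed genes BBA_04720 and BBA_05166 had 9209 and 8429 FPKM at 0 h and none at 24 h.

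Zinc cluster factors and autophagy genes were lower at 24 h as lists. Zinc cluster transcription factors, a family of regulators particular to fungi, took 2.53-fold fewer reads (2.13 to 2.99), with 18 of 142 compared members lower and 1 higher by the interval (median log2 -1.33, percentile 0.010). BBA_07683, BBA_04784 and BBA_09096 stood at 179, 166 and 152 FPKM at 0 h and were listed at 0 at 24 h. Autophagy genes took 3.47-fold fewer reads (2.07 to 5.79), with 2 of 15 lower by the interval (percentile 0.29). Sugar transporters were 2.26-fold lower (1.63 to 3.16), with 7 of 30 lower and none higher, among them BBA_07095 (225 and 0 FPKM), BBA_06639 (136 and 0) and BBA_00675 (134 and 0). Their median (log2 -1.54, percentile 0.80) did not stand apart with a minimum of 20 FPKM (percentile 14.7) or under TMM scaling, where the interval of the pooled ratio, 0.779, included 1. The list of ABC and multidrug transporters, which also holds MFS members, had a lower median too (log2 -1.31, percentile 0.71, but 29.1 with a minimum of 20 FPKM), with 6 of 42 members lower and 1, the MFS transporter BBA_04706, higher, while its pooled ratio of 0.794 (0.654 to 0.963) ranged from 0.582 to 1.40 across scalings. Beside these, the named genes higher at 24 h and listed at 0 at 0 h were CipC (BBA_06439, 1743 FPKM), an allantoicase-like gene of purine breakdown (BBA_08733, 1574), a nuclear transport factor 2 domain gene (BBA_02851, 1476), an antigenic cell wall galactomannoprotein (BBA_02996, 1373), Mmc (BBA_04710, 1289) and the unnamed BBA_07240 (3051) and BBA_06201 (2252).

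By the size rule, 4-fold on the log2(FPKM + 1) scale among the 7247 genes with a mean of at least 5 FPKM, 2121 genes were higher and 1728 lower at 24 h than at 0 h, and with an interval excluding 1 the numbers were 284 and 517. Libraries drawn with no difference gave a mean of 1809 and 546 by size and 11.1 and 47.2 with the interval, and 1888 of the genes higher by size were listed at 0 at 0 h. The split depended on scaling: trimmed-mean (TMM) scaling gave 2426 and 1290 by size and 570 and 181 with the interval, median-of-ratios scaling 457 and 280 with the interval, and totals without conserved genes 180 and 652.

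At 48 h of infection the oosporein genes stood out against the library labelled 0 h. Oosporein is a red pigment made by this fungus in the insect, and its 7 neighbouring genes (BBA_08179 to BBA_08185) took 28954 RPM at 48 h against 427 at 0 h, 67.9-fold more (37.4 to 155). All 7 were higher with an interval excluding 1 (median log2 5.98, percentile 98.7). The polyketide synthase BBA_08179, which builds the carbon skeleton, had 34.3 FPKM at 0 h and 2243 at 48 h, a ratio of 65.3 (25.7 to 185). The glutathione S-transferase BBA_08184 had 73.0 and 8902 FPKM, the FAD-binding gene BBA_08182 had 36.3 and 2351, and the laccase BBA_08183 had 26.1 and 1620.5. The transcription factor BBA_08181 of the cluster was listed at 0 at 0 h and at 212 FPKM at 48 h. Polyketide and nonribosomal peptide synthases as a list took 10.4-fold more reads (7.43 to 15.0), mostly through BBA_08179, which is also a member: without it the ratio was 1.82 (1.25 to 2.66), and the median of the list did not stand apart (percentile 89.3). Of 10 compared members 5 were higher and 2 lower, one of the latter being the siderophore synthase SidC BBA_05179 (43.0 and 0.80 FPKM, with an estimated 3.4 reads at 0 h).

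Single genes for proteases, LysM proteins and a CFEM domain protein were also higher at 48 h. The chymotrypsin-like protease BBA_03951 had 32.6 FPKM at 0 h and 6479.8 at 48 h, but the ratio of 199 rested on about 1 read at 0 h (29.95 to 6596). The trypsin-like BBA_03203 was listed at 0 and at 209 FPKM. LysM proteins, whose domain binds chitin, took 18.6-fold more reads (4.64 to 139), or 8.59-fold (2.14 to 64.4) without BBA_08602, and a median just within the random range (percentile 97.3), with BBA_08602 at 0 and 1608 FPKM and BBA_03138 at 38.0 and 424 FPKM, both with intervals excluding 1. These folds too rested on few reads at 0 h, where the list held 82.0 RPM (11.0 to 327). BBA_03138, with an estimated 1.0 read, held 54.3% of it. The CFEM domain gene BBA_09339 had 80.0 and 7035 FPKM, and it alone set the pooled reads of the surface receptor list 5.72-fold higher (3.6 to 9.36) while the median of that list was lower (log2 -4.64, percentile 0.0, 5 of 10 members lower by the interval, for example BBA_06341 with 98.7 and 0 FPKM). Laccase and pigment genes had a median log2 of 5.82 (percentile 99.96, but 87.25 without the minimum and 92.7 with a pseudocount of 0.1), with 3 of 7 compared members higher and none lower. Their pooled ratio was 28.5 (10.7 to 101), and 16.3 (5.30 to 75.3) without the laccase BBA_08183 of the oosporein cluster. It also rested on few reads at 0 h, where the list held 175 RPM (49.4 to 464).

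Ribosomal proteins took 3.80-fold more reads than at 0 h (3.54 to 4.09), glycolysis genes 3.04-fold (2.36 to 3.97), proteasome genes 1.96-fold (1.49 to 2.61) and the respiratory chain 1.95-fold (1.76 to 2.16), with 34 of 111, 6 of 21, 4 of 37 and 12 of 64 members higher by the interval and 2, 1, 0 and 3 lower. The medians of the ribosomal and proteasome lists stood apart, and those of glycolysis (percentile 96.5) and the respiratory chain (62.8) did not. Cytochrome c oxidase polypeptide IV (BBA_08770) was listed at 0 at 0 h and at 1422 FPKM at 48 h. Zinc cluster factors were 2.24-fold lower (1.97 to 2.54), with 33 of 142 members lower and 1 higher. Conidiation genes were 6.29-fold lower (5.16 to 7.61), again through the conidial wall proteins, without which the ratio was 0.979 (0.465 to 2.85). Cytochrome P450 genes, a family of oxidising enzymes, had a lower median (log2 -1.62, percentile 0.0) with 13 of 41 members lower and 3 higher, and BBA_05439 (329.7 and 2.22 FPKM) and BBA_02823 (278 and 4.12) stood against BBA_08425 (0 and 358.5). Without the filter on low values that median was positive, 1.07, and the pooled ratio of 0.601 (0.496 to 0.740) ranged from 0.414 to 1.14 across scalings.

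Among single genes, the highest at 48 h and listed at 0 at 0 h included a DUF1275 domain gene (BBA_06347, 1283 FPKM) and alpha-amylase A (BBA_05376, 1086), and without a functional name BBA_09872 (6755) and BBA_06283 (5085). The low end held the same spore genes, with BBA_03015, BBA_03994 and BBA_09998 listed at 0, and again the Bys1 family BBA_03338, at 3.92 FPKM. Further genes there were a peroxisomal enzyme (BBA_00952, 507 and 0 FPKM), a short-chain dehydrogenase (BBA_06007, 506 and 0) and an MFS transporter (BBA_05666, 459 and 0). An antifungal protein (BBA_08974, 388 and 0) and an alcohol dehydrogenase (BBA_06625, 367 and 0) rested on an estimated 2.5 and 6.6 reads at 0 h.

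Counted by size, 2490 genes were higher and 1398 lower at 48 h than at 0 h, and with the interval 350 and 777. Draws with no difference gave 2737 and 271 by size, so the number higher by size was no more than counting noise gives, and 7.99 and 48.5 with the interval. TMM scaling gave 2919 and 785 by size and 811 and 409 with the interval, median-of-ratios scaling 597 and 525 with the interval, and totals without conserved genes 199 and 1169.

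At 72 h, when the host was labelled dead, ribosomal proteins took 4.26-fold more reads than in the library labelled 0 h (3.97 to 4.58), with 43 of 111 members higher and 2 lower, and the oosporein genes 25.1-fold more (13.8 to 57.4), with all 7 higher. The LysM ratio of 18.6 at 48 h had no counterpart at 72 h, where it was 1.41 and its interval included 1. Iron acquisition genes were 5.28-fold higher in pooled reads (3.73 to 7.91) with a median within the random range (percentile 79.4), led by BBA_05827 with 2376 FPKM, without which the ratio was 2.58 (1.82 to 3.88), though only 3 of 27 compared members were higher by the interval and 4 lower. The chitinase-like gene BBA_03814 reached 1813 FPKM and the cytochrome P450 BBA_04705 reached 831, both listed at 0 at 0 h. The medians of both their lists nevertheless stood apart lower at 72 h. That of P450 genes did so under every alternative. Their pooled ratio of 0.715 had an interval excluding 1 but ranged from 0.479 to 1.32 across scalings. The chitinase median was at percentile 10.1 without the minimum, and the interval of the pooled chitinase ratio, 1.46, included 1. The adhesin BBA_03909 had 131 and 2892 FPKM, a ratio of 22.1 (6.07 to 182) that rested on an estimated 2.0 reads at 0 h. Zinc cluster factors were 2.22-fold lower (1.96 to 2.51), with 33 of 142 lower and 1 higher, and conidiation genes 5.19-fold lower (4.27 to 6.25), with a ratio of 0.842 (0.401 to 2.47) without the 3 conidial wall proteins.

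Further genes listed at 0 at 0 h and high at 72 h were an MFS transporter (BBA_00065, 1261 FPKM), the anaphase-promoting complex subunit Apc5 (BBA_07742, 974) and the unnamed BBA_09872, whose 41722 FPKM came after 568 at 24 h and 6755 at 48 h. A short-chain dehydrogenase (BBA_09597, 319 FPKM and an estimated 6.0 reads at 0 h) was listed at 0 at 72 h, and so was a glycoside hydrolase of family 55 (BBA_04013, 316 FPKM at 0 h). Histones as a list did not stand apart, with H2B (BBA_09945) at 720.1 and 2963 FPKM and an H4 variant (BBA_08810) at 104 and 6.47. Size alone gave 2467 genes higher and 1398 lower, against 2729 and 264 in draws with no difference, and the interval left 334 and 758, against 7.63 and 42.4 in the draws. TMM scaling gave 2873 and 848 by size and 780 and 451 with the interval, median-of-ratios scaling 553 and 557 with the interval, and totals without conserved genes 176 and 1198.

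The 3 infection times had many genes in common in their difference from 0 h. With the interval, 182 genes were higher and 367 lower at all 3 times, where independent lists of those sizes would share 0.632 and 5.80 and draws with no effect from the shared 0 h library gave 2.80 and 9.13. By size the numbers were 1899 and 979, with 248 and 64.3 for independent lists and 1750 and 122 in the draws. The 0 h library cannot be split, so part of the excess may come from it.

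**Figure D2:**
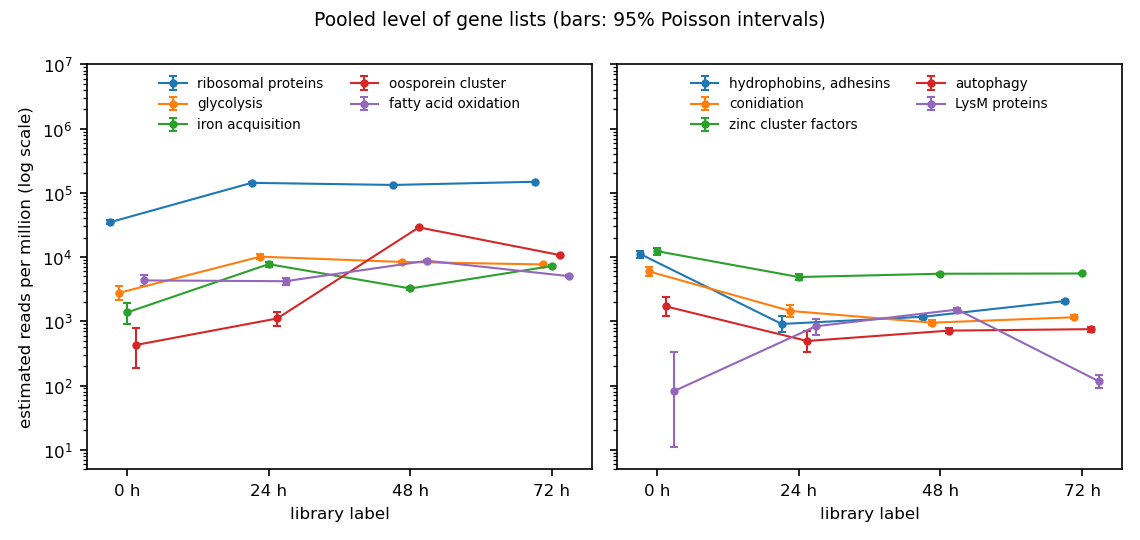
Pooled RPM on a log scale for 10 gene lists in each library, by label, with 95% Poisson intervals for counting error. Ribosomal proteins went from 34847 at 0 h to 143041, 132571 and 148596, the oosporein cluster from 427 to 1106, 28954 and 10695, and LysM proteins from 82.0 (11.0 to 327) to 836, 1523 and 116.

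From 24 to 48 h of infection, both in hosts labelled live, the oosporein genes showed the greatest difference of any list. Their pooled reads were 26.2-fold higher at 48 h (20.5 to 34.1), all 7 members passed the rule with the interval, and the median log2 of 4.45 was above every random list drawn. BBA_08179 was 29.6-fold higher (20.7 to 46.4), BBA_08184 20.02-fold (12.5 to 38.6) and BBA_08183 54.4-fold (19.04 to 271). A second run of neighbouring genes was higher too: the nonribosomal peptide synthase BBA_08222 had 2.37 FPKM at 24 h and 62.1 at 48 h, a ratio of 26.2 (6.31 to 189.7), the acetyltransferase BBA_08220 had 11.9 and 227, and the ligase BBA_08221 had 11.2 and 218. The protease BBA_03951 was 43.6-fold higher (23.8 to 91.6).

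Genes that use fatty acids were higher at 48 h than at 24 h as a list. Fatty acid oxidation and glyoxylate genes took 2.08-fold more reads (1.83 to 2.37), with a median log2 of 0.96 (percentile 99.9). Of 29 compared members 2 were higher and none lower, among them the carnitine acyltransferase BBA_05592 (13.3 and 102 FPKM, 7.65-fold, 1.83 to 56.1). Part of the pooled rise came from BBA_01125, which held 32.5% of the list's reads at 24 h and 47.5% at 48 h. Listed at 0 at 24 h were the terpene enzyme longiborneol synthase (BBA_08897, 549 FPKM at 48 h), the HIT domain gene BBA_10210 (288), zinc-binding dehydrogenase BBA_08949 (283), a methyltransferase (BBA_06327, 253), an LSM domain gene (BBA_00340, 241) and the unnamed BBA_07222 (491) and BBA_09619 (186).

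Exopeptidases went the other way, 1.46-fold lower in pooled reads (1.29 to 1.65) with a median log2 of -0.39 (percentile 0.35) and 3 of 31 compared members lower and none higher. Tripeptidyl peptidase BBA_07294 was 15.1-fold lower (9.16 to 23.5). The subtilisin-like PR1F gene BBA_07143 had 111 FPKM at 24 h and was listed at 0 in all other libraries, and PR1F BBA_09501 had 129 at 24 h and 1.79 at 48 h. The S53 protease BBA_07631 was 74.1-fold lower (32.1 to 165), and the multidrug transporter BBA_04706 78.6-fold (35.1 to 235). DUF300 domain gene BBA_08792 had 144 and 1.28 FPKM. The GTP-binding protein BBA_04717 and the unnamed BBA_03795 and BBA_07148 had 68.9, 162 and 139 FPKM at 24 h and none at 48 h. Those values at 24 h rested on an estimated 3.2, 1.6 and 3.2 reads. Iron acquisition genes were 2.39-fold lower in pooled reads (2.16 to 2.65), with BBA_04575 3.48-fold lower (2.52 to 4.41), and a median that stayed within the random range (percentile 4.41). Glycolysis genes were slightly lower (1.21-fold, 1.11 to 1.32, percentile 2.05, but 3.0 with the top 1% of genes left out of the totals), with no member passing the rule with the interval. Ribosomal proteins had a median of -0.10 (percentile 1.31), which TMM scaling turned to 0.02.

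In this comparison 1323 genes were higher and 357 lower by size, against 1302 and 151 in draws with no difference, and 125 and 178 with the interval, against 18.6 and 30.9. The 24 h library had 57999 estimated reads against 594893 at 48 h, and 1189 of the higher genes were listed at 0 at 24 h.

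The comparison of 72 with 48 h, across the labels dead and live, had the deepest libraries and the narrowest intervals. Here 32 genes were higher and 149 lower by size with the interval, against 10.8 and 8.86 in draws with no difference. The run BBA_08219 to BBA_08222 was low again at 72 h: the polyketide synthase BBA_08219 was 157-fold lower (38.6 to 1168), the acetyltransferase BBA_08220 68.3-fold (19.2 to 280.2), the ligase BBA_08221 41.7-fold (19.4 to 118) and the synthase BBA_08222 28.1-fold (17.9 to 50.1). The oosporein genes were 2.71-fold lower in pooled reads (2.63 to 2.79), with a median log2 of -1.22 (percentile 0.155); BBA_08179, 4.10-fold lower (3.92 to 4.32), was the only one of the 7 past the 4-fold rule. The list of polyketide and nonribosomal peptide synthases, of which BBA_08179 is also a member, was 3.85-fold lower (3.69 to 4.03), with 4 of 10 compared members lower by the interval and none higher (percentile 0.89, but 4.8 without the minimum). Without BBA_08179 it was 2.85-fold lower (2.58 to 3.15). The nonribosomal peptide synthase BBA_03671 was 11.4-fold lower (6.94 to 18.9).

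LysM proteins were 13.1-fold lower at 72 than at 48 h (10.3 to 17.0), or 7.68-fold (5.82 to 10.3) without BBA_08602, and 3 of 4 compared members passed the rule with the interval (median log2 -3.24, percentile 0.0). BBA_08602 was 33.8-fold lower (20.4 to 61.2), BBA_03138 17.5-fold (10.8 to 29.8) and BBA_09350 5.46-fold (3.20 to 9.71). Tyrosinase 2 BBA_04061 was 17.3-fold lower (13.2 to 23.2), protease BBA_03951 9.29-fold (8.48 to 10.2), the subtilisin PR1C BBA_09153 39.0-fold (21.2 to 73.1) and the carboxylic acid transporter BBA_06536 51.7-fold (12.5 to 390.3). The unnamed BBA_05436 and BBA_01460 had 117 and 42.8 FPKM at 48 h and none at 72 h. Fatty acid oxidation genes were 1.74-fold lower (1.66 to 1.81), with 2 of 29 members lower and 1 higher, but 1.18-fold (1.12 to 1.25) without BBA_01125. Their median (percentile 2.48) did not stand apart with the top 1% of genes left out of the totals (percentile 2.9). The respiratory chain had a lower median (log2 -0.19, percentile 0.03) with no member past the rule.

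Higher at 72 than at 48 h was a dehydrogenase acting on glutamate and related amino acids, BBA_00775, at 34.9 and 359 FPKM, a ratio of 10.3 (7.13 to 15.9). The P450 BBA_04705 was 6.25-fold higher (5.18 to 7.51), the siderophore transporter BBA_05827 3.15-fold (2.89 to 3.43) and the adhesin BBA_03909 2.04-fold (1.84 to 2.25). Iron acquisition genes took 2.24-fold more reads (2.12 to 2.36), although no single member passed the rule upward. Ribosomal proteins took 1.12-fold more (1.11 to 1.13, percentile 98.9), again with no member past the rule, and the cell wall synthesis list had a higher median (log2 0.30, percentile 98.4, but 96.3 with a pseudocount of 5) while its pooled reads were 1.05-fold lower (0.99 to 1.11). The unnamed BBA_09673 was listed at 0 at 48 h and at 13.2 FPKM at 72 h. Of the other genes named at the high end by the rule, BBA_09887, BBA_03580, BBA_03302, BBA_07630 and BBA_10120, all listed at 0 at 48 h and at 7.70 to 17.9 FPKM at 72 h, had intervals that included 1. Size alone gave 80 higher and 219 lower, against 61.3 and 57.4 in the draws.

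**Figure D3:**
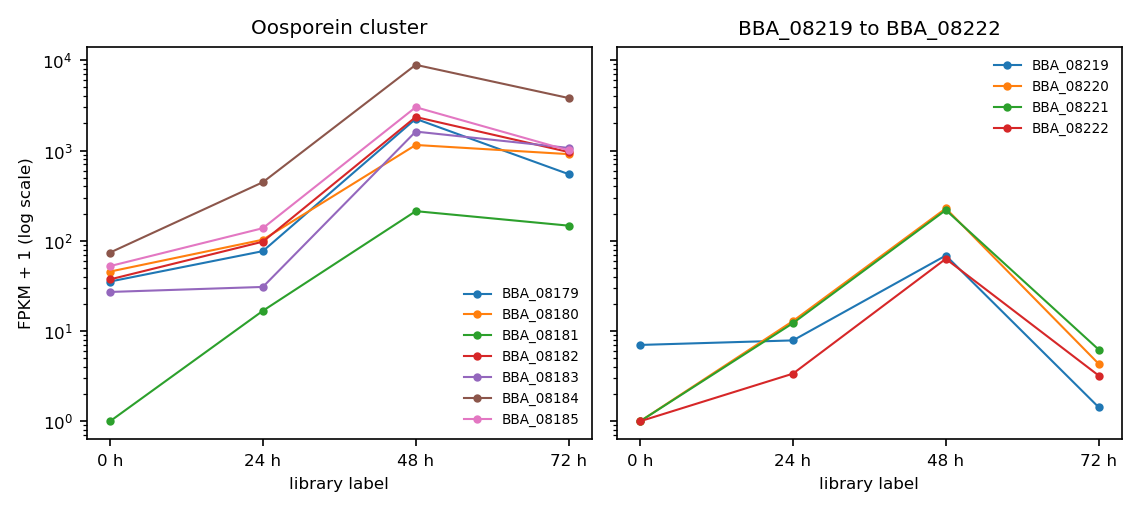
FPKM + 1 on a log scale in each library, by label, for the 7 genes of the oosporein cluster (left) and for BBA_08219 to BBA_08222 (right), 1 line per gene and 1 library per point. All 11 genes are highest at 48 h, where BBA_08184 reaches 8902 FPKM and BBA_08220 reaches 227.

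Across the 35 lists, 4 stood higher and 8 lower than random lists at 24 h against 0 h, 4 and 6 at 48 h, 4 and 7 at 72 h, 2 and 3 from 24 to 48 h, and 2 and 5 from 48 to 72 h. Aspartic proteases, metalloproteases, antioxidant enzymes, heat shock proteins and chaperones, trehalose and mannitol enzymes, amino acid and peptide transporters, histones, toxins, MAP kinase signalling and cell cycle genes had medians that stood apart in none of the 5 comparisons, and so had the subtilisin-like, trypsin-like, hydrophobin and adhesin, and conidiation lists, whose pooled reads or single genes are given above. Heat shock proteins and chaperones, for example, took 18458 RPM at 0 h and 22924, 23369 and 24099 at the infection times. Their pooled ratios of 1.24, 1.27 and 1.31 had intervals excluding 1. These ranged from 0.910 to 2.19, 0.873 to 2.40 and 0.875 to 2.41 across scalings. A single gene held 48.7% of the list's reads at 0 h and 29.8%, 25.6% and 25.8% later. The other members, pooled, thus rose more than these ratios.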

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

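The tests with the interval, with genes above 0 in both libraries, with conserved genes left out of the totals and with genes left out of pooled lists were chosen after the results were seen, and the cause of a moved count was not tested unless stated. No paired analysis was possible because each group was 1 library. Counts are given as higher and lower at 24, 48 and 72 h against 0 h, then 48 against 24 h, then 72 against 48 h. By size they were 2121 and 1728, 2490 and 1398, 2467 and 1398, 1323 and 357, and 80 and 219, with 1899 higher and 979 lower at all 3 times. Requiring the interval gave 284 and 517, 350 and 777, 334 and 758, 125 and 178, and 32 higher, with 182 and 367 at all 3 times. Because the libraries differ in depth, the interval is stricter for genes higher in the deeper library. BBA_08974, with an estimated 2.5 reads at 0 h and 0 at 48 h, passed as lower. BBA_09350, with 0 at 0 h and 88.2 at 48 h, did not pass as higher. Genes above 0 in both libraries gave 233 and 676 at 24 h, 242 higher at 48 h, 245 higher at 72 h, and 134 and 38 higher between the successive times. A minimum of 20 FPKM, which compares fewer genes, gave 1324 and 1149, 1389 higher, 1390 higher, 617 and 169, and 46 higher, with 1227 and 637 at all 3 times. A 2-fold rule, wider by construction, gave 2373 lower at 48 h, 2368 lower at 72 h, 2032 and 1023, 450 and 707, and 1857 lower at all 3 times. A pseudocount of 5 gave 691 and 211 and 13 and 111 between the successive times and 1252 higher at all 3 times. A pseudocount of 0.1 gave 142 higher from 48 to 72 h, and no minimum gave 156. TMM scaling gave 785 lower at 48 h, 848 lower at 72 h and 528 lower at all 3 times. All other counts from these alternatives stayed within 1.5 times of those by size. Counts with the interval, compared with one another across scalings, moved further. At 24, 48 and 72 h against 0 h, TMM scaling gave 570 and 181, 811 and 409, and 780 and 451 with the interval. Totals without conserved genes gave 180 and 652, 199 and 1169, and 176 and 1198.

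Against 0 h, the median-of-ratios and TMM scalings shifted all log2 ratios by 0.52 to 0.56 and by 0.82 to 0.93, and leaving out the top 1% of genes or the conserved genes shifted them by -0.11 to -0.21 and by -0.45 to -0.58. The median-of-ratios and TMM scalings use only genes above 0. Over compared genes above 0 in both libraries, the median log2 ratio at 24, 48 and 72 h against 0 h was -0.39, -0.84 and -0.85. Over all compared genes it was 0.0, 0.051 and 0.075. Between 48 and 72 h no scaling shifted the log2 ratios by more than 0.051. Of 175 list medians, 45 stood apart, 23 of them under each of the 7 alternatives set beforehand that bear on a median (the 2-fold rule does not) and under the added scaling without conserved genes; 103 of the other 130 never did. The median turned for P450 genes at 48 h without a minimum (1.07), and under TMM scaling for ABC and multidrug transporters at 48 h (0.14), ribosomal proteins from 24 to 48 h (0.022) and conserved genes at 48 and 72 h (0.028 and 0.016). Depth limits the 0 h library most.

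Of 175 pooled ratios of lists, 125 had an interval excluding 1. With the gene of largest change left out, 83 of these kept it on the same side, 21 kept only the direction and 21 turned, so pooled ratios often rested on 1 gene. At 24, 48 and 72 h against 0 h, the ratio turned to 3.34, 4.33 and 7.597 for hydrophobins and adhesins and to 0.207, 0.149 and 0.227 for surface receptors. It turned to 0.830 for trypsin-like proteases at 24 h, and at 72 h to 0.638 for synthases and 0.999 for antioxidant enzymes. From 24 to 48 h it turned to 1.01 for subtilisin-like proteases, 0.468 for trypsin-like proteases, 0.966 for antioxidant enzymes, 0.916 for laccases, 1.29 for conidiation and 0.723 for surface receptors. From 48 to 72 h it turned to 0.964 for exopeptidases, 0.431 for chitinases, 0.765 for P450 genes, 0.378 for hydrophobins and adhesins, 0.864 for conidiation and 0.847 for conserved genes. Without the conidial wall proteins BBA_03994 and BBA_09998 the conidiation ratio turned to 4.46, 2.93 and 3.55 against 0 h, which rested on another, BBA_07138. Without all 3 it was 0.758, 0.979 and 0.842, with intervals including 1, and turned to 1.29 from 24 to 48 h and 0.860 from 48 to 72 h.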

Other observations

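The tests of actin and of the conserved list against the clean reads, of the share of clean reads, and of the oosporein genes against random lists, were chosen after the results were seen; the other tests below were set before their results.

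Genes of cell wall construction, not described above for the early time, took 1.87-fold more pooled reads at 24 h than at 0 h (1.37 to 2.68), or 1.53-fold (1.10 to 2.19) without BBA_03990, while their median did not stand apart (percentile 71.3), and 3 of 25 compared members were higher and 2 lower with an interval excluding 1. The glucanosyltransferases BBA_03990 and BBA_08600, which remodel wall glucan, were listed at 0 at 0 h and stood at 515 and 166 FPKM at 24 h, 147 and 113 at 48 h and 192 and 148 at 72 h. A run of neighbours chosen after its values were seen, BBA_05173 to BBA_05175, was high at 24 h: the P450 BBA_05173 had 66.7 FPKM at 24 h and 9.76 at 48 h, BBA_05174 had 384 and 7.94, and the LCCL domain gene BBA_05175 had 556 and 9.56. BBA_02338 to BBA_02340, around a taurine dioxygenase, went the other way, with 70.5, 35.2 and 62.4 FPKM at 24 h and 556, 346 and 647 at 48 h.

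The first pattern is that actin and tubulin took 25.6% of the reads in the library labelled 0 h. Shallow sampling of the transcripts seen at 72 h is argued against, since thinning the 72 h reads to the 0 h total gave at most 1.495% in 100 draws. Thinning keeps the 72 h share on average, so this shows only that the libraries differed in composition beyond sampling. A pure culture with every clean read offered to the gene models is also argued against, because 0.0938% of the clean reads fell on fungal genes. Actin and tubulin stood at 239.7, 291, 429 and 341 RPM of clean reads, at most 1.79-fold apart, while the total on fungal genes was 28.2-fold apart, which insect RNA in all 4 libraries could give if its reads matched these genes. Insect reads matching all of the conserved list alike are argued against, since its other 22 genes rose 30.8-fold from 0 to 72 h per clean read, with the fungal total. Which insect transcripts would match was not tested, so the source of the actin and tubulin reads stays open. Whether the library labelled 0 h was a plate culture, spores on an insect or a sorted set of reads stays open, and so does how much of each ratio against it is growth on agar.

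The second pattern is the number of genes higher at 48 h than at 0 h. Counting noise could account for the count by size, since draws with no difference gave 2737 genes on average and 2490 were observed. It is argued against for the 350 genes whose interval excludes 1, since the draws gave 7.99. For those genes a difference between growth on agar and in the host stays open as a hypothesis, with the origin of the 0 h library unsettled.

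The third pattern is the oosporein cluster at 48 h. The lower depth of the 24 h library is argued against: thinned to its total, the 48 h reads left at least 1580.0 reads on the 7 genes in 100 draws, and 64.1 were estimated at 24 h. Thinning keeps the 48 h share on average, so this shows only that the share of these genes differed between 24 and 48 h beyond sampling. It adds nothing to the pooled ratio. A change of the totals between 48 and 72 h is argued against as well, since it would move every gene alike, while the median of the 7 genes at 72 against 48 h lay at percentile 0.155 of random lists of the same level. A peak of oosporein transcripts near the time of death may therefore be biological, as a hypothesis from 1 library per time that no replicate bears on.

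It was asked whether genes that differ between 48 and 72 h stand next to each other on the genome. The 149 genes lower at 72 h formed 21 adjacent pairs in locus tag order, against a mean of 2.39 and a highest value of 10 in 10000 random orders, which fits neighbouring genes changing together. Runs of at least 3 were BBA_05289 to BBA_05291, BBA_05347 to BBA_05349, BBA_06333 to BBA_06335, BBA_08219 to BBA_08222 and BBA_09488 to BBA_09490. The 32 genes higher at 72 h formed 1 adjacent pair, within the 3 reached by random orders, and were too few to decide.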
